A study of Mus musculus with 2 samples.

How the data were processed

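Xenium in situ data of 2 liver sections from 2 mice, 1 zone 3 mutant and 1 wild type, were analysed. Per the labels' protocols, livers were fixed in formalin, embedded in paraffin, assembled in tissue panel blocks and cut at 5 µm, and the probe set was made with Designer version 3.5.0. The deposited matrices hold raw counts of decoded transcripts per feature and segmented cell, per the file headers and from the whole-number values. The method of cell segmentation, the instrument software, the quality threshold for transcripts and any selection of cells are not given in the sources used here. Gene symbols and Ensembl identifiers were taken from the deposited feature lists, and no genome was used. The panel had 440 genes, 20 negative control probes, 41 negative control codewords and 40 unassigned codewords. Control features were kept out of all totals. Each mouse's sex, feeding state and hour of collection, and whether the wild type received tamoxifen, are not given in the sources used here.

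Cells with at least 10 panel transcripts were kept, which left out 447 mutant and 617 wild-type cells. Counts were scaled per cell, log-transformed and standardised per gene, without the pericentral, periportal and beta-catenin lists. Then 30 principal components and 15 nearest neighbours were used for Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1) of 20000 cells per section together, and every other cell took the majority cluster of its 15 nearest clustered cells. This gave 17 clusters. A cluster was named "-like" a class when that class alone had the most fixed markers among its 10 leading genes by fold, at least 2, with at least 3 markers above the other cells, and when its first leading gene was not a marker of another class alone. The clusters that stayed unnamed were led by cell cycle genes, by Cxcl9 and Cxcl10, by Siglech, or had a median of 54 and 51 transcripts per cell. No doublet caller was run, since segmented cells are not droplets. Transcripts of a neighbour inside a cell's outline remain a limit for every class, and most for the shallow ones.

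Counts were summed per section and class. Expression was given as CPM of the class's panel counts, and folds with exact conditional (Clopper-Pearson) 95% intervals, shares with exact binomial ones. These cover counting error only, and with 100674582 and 122789613 panel transcripts they are far narrower than differences between mice can be. With 1 mouse per group no test was made and no p-value is given. A gene was described as higher or lower when its fold was at least 2, with at least 100 counts over both sections and, in the higher section, at least 5 times the mean negative control probe count. The genes named were fixed by rule before the data were examined: the targeted genes and Glul, the 12 largest folds in each direction in hepatocyte-like cells, up to 4 members with most counts of each hepatocyte list, the 5 largest folds of the whole section not named before, up to 3 members of each marker list, the 4 largest folds in each direction of each other class with at least 200 cells per section, and 12 zonation genes. Genes chosen outside the rule are said to be. All gene lists and markers were fixed at the same time. A list's median log2 fold was set against 10000 random lists of the same size, matched on mean expression in 5 bins. For zonation, hepatocyte-like cells were thinned to 50 transcripts and ranked by log2 of (pericentral + 1) over (periportal + 1) transcripts, without Glul and without the gene described. Bin levels use all transcripts of the cells.

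The steps were tested on data simulated from the real gene means and library sizes, with 200 of 440 genes changed. In the simulated hepatocyte comparison, all genes above the floor were called on the side of 2-fold where their true CPM ratio lay, and the 95% intervals held the true ratio for 97.0% of 334 genes. The simulated counts held Poisson error only, with no transcripts of neighbours, no background and no other difference between sections. At this depth such calls could hardly fail, so the simulation checks the computation and not those sources of error. Since CPM values share 1 total, genes planted at 2.5-fold had a CPM ratio of 1.92 and unchanged genes one of 0.768, so folds are relative to the rest of the panel. A simulated gene with 54.5% of its transcripts in the true top 10% of cells had 39.0% in the top bin, so bins at this depth blur sharp borders. Alternatives to the scaling, cell filter, count floor, class definition, clustering, thinned depth, index genes, class rule and random lists were computed, with TMM factors from edgeR 4.0.16 in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Cell coordinates and the panel description were not used here.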

Results

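The livers of 2 mice were profiled in situ with Xenium, an imaging assay that decodes single transcripts inside tissue sections and assigns them to segmented cells. The custom panel held probes for 440 mouse genes and was run on 5 µm sections of formalin-fixed, paraffin-embedded tissue. The zone 3 mutant mouse carried Cyp1a2-CreERT2, a tamoxifen-inducible recombinase driven from a gene of hepatocytes around the central vein, which is the region called zone 3. It also carried a Ctnnb1 allele with a floxed exon 3, whose loss stabilises beta-catenin, a floxed allele of the chromatin remodeler subunit Arid2, and a Cre-dependent tdTomato reporter. Tamoxifen was given at postnatal day 28 and the liver was collected 1 month later. The control was 1 age-matched wild-type animal. The mutant was of mixed C57BL/6J and Swiss Webster background and the wild type was C57BL/6J. A zone 1 model named in the series' design was not analysed here.

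The mutant section held 121919 cells and 100674582 panel transcripts, and the wild-type section held 156456 cells and 122789613 panel transcripts. After cells with fewer than 10 transcripts were left out, 121472 and 155839 cells remained, with medians of 713 and 670 transcripts and 131 and 128 genes per cell. With 1 mouse per group there was no replicate check and no test. All intervals are 95% intervals for counting error only, and the values compare these 2 sections. Single genes are counted as higher or lower by a fixed rule of size, at least 2-fold, lists are described by their medians, and folds are mutant over wild type unless stated otherwise.

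The targeted genes were compared first. In hepatocyte-like cells, Ctnnb1 (encoding beta-catenin) was at 1697 CPM (panel counts scaled to the same total in each section) in the mutant and 1726 in the wild type, a fold of 0.983 (interval 0.977 to 0.990). Arid2 was at 403 and 413 CPM, a fold of 0.975 (0.962 to 0.989). Cyp1a2, the gene that drives the recombinase, was at 10259 and 10288 CPM, a fold of 0.997. With mean transcripts per cell or TMM scaling, these 3 folds lay between 1.00 and 1.03, so their direction depended on the scaling. Among cells with at least 5% Glul transcripts, a group chosen after values were seen, Ctnnb1 was at 2161 against 1294 CPM, a fold of 1.67 (1.63 to 1.71), and Arid2 was at 345 against 309 CPM, a fold of 1.12 (1.07 to 1.17). For this group Glul was left out of the totals, so its CPM levels are not on the scale of those above. The positions of the probes relative to the floxed parts are not given in the sources used here, so these levels check nothing about recombination. The panel held no probe for tdTomato or Cre.

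Beta-catenin targets and genes of pericentral hepatocytes were higher in mutant than in wild-type hepatocyte-like cells, while periportal genes went both ways. Glul, which encodes glutamine synthetase and marks the hepatocytes next to the central vein, was at 25868 CPM against 14176, a fold of 1.82 (1.82 to 1.83). The Wnt feedback inhibitor Axin2 was 2.71-fold higher (2.66 to 2.77), the R-spondin receptor Lgr5 2.57-fold (2.52 to 2.63) and the ubiquitin ligase Rnf43 2.11-fold (2.07 to 2.16). Of the 15 beta-catenin targets above the count floor, 13 had a fold above 1 and 4 met the size rule, with a median log2 fold of 0.79. This median was at percentile 100 among 10000 random lists matched on mean expression, a description of these sections rather than a test. Of the 18 pericentral genes, 17 had a fold above 1 and 5 met the rule, with a median of 0.69, also at percentile 100. The 5 include Cyp2a5, whose separate level is uncertain because its probes could share transcripts with those of Cyp2a4. The lists overlap, with 10 genes in both. Of the pericentral genes with most counts, Cyp2e1 was at 1.41-fold (1.41 to 1.42), the transporter Slco1b2 at 1.22-fold and Cyp1a2 at 0.997. Oat, encoding ornithine aminotransferase, was at 1.72-fold (1.71 to 1.73). Of 14 periportal genes 9 had a fold below 1 and 0 met the rule, with a median of -0.13 at percentile 4.99, inside the range of the middle 95% of random lists. Among the most periportal cells that median was 0.06. Among the most pericentral cells it was -0.73, with 10 genes lower and 4 higher. These cells were ranked within each section by a score that holds the other periportal genes. The 90th percentile of that score was 2.22 in the mutant and 0.778 in the wild type. The value of -0.73 therefore does not compare matched zones and can follow from the ranking. Over all hepatocyte-like cells, Ass1 and Cps1, enzymes of the urea cycle, were at 0.817 and 0.856, Pck1 of gluconeogenesis at 0.708 and Hpd at 1.09. The periportal list shares 8 genes with that of urea cycle and amino acid catabolism. Different clusters held most hepatocyte-like cells of each mouse. Clusters 2, 5 and 6 held them in the mutant and clusters 1, 4 and 9 in the wild type.

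Genes of lipid synthesis were lower in the mutant hepatocyte-like cells. Fasn, which encodes fatty acid synthase, was at 4331 CPM against 13462, 3.11-fold lower (3.10 to 3.12). Me1, encoding malic enzyme, was 3.24-fold lower (3.23 to 3.26), and Acly, encoding ATP citrate lyase, 2.08-fold lower (2.08 to 2.09). All 9 measured genes of the lipid synthesis and storage list had a fold below 1 and 3 met the rule. Their median log2 fold was -0.39, at percentile 0.14. Mlxipl, a transcription factor that responds to carbohydrate, was at 0.812. G6pdx, which encodes the first enzyme of the pentose phosphate pathway, was 5.34-fold lower (5.14 to 5.55), and the fatty acid binding protein gene Fabp5 was 2.73-fold lower (2.71 to 2.74). Of 8 genes of glucose metabolism 6 had a fold below 1 and 1 met the rule, with a median of -0.41 at percentile 0.11. Among them G6pc was at 0.512, Gapdh at 0.884 and the glucose transporter Slc2a2 at 1.03, and 2 of the 8 are also on the periportal list.

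Tumor and fetal liver genes had a median of 0.56 at percentile 99.1 over 6 genes, of which Robo1 was at 1.81, Sox9 at 0.854 and Nqo1 at 0.949. That median depended on the settings, at 0.13 when hepatocytes were defined by a per-cell marker rule and -0.12 over the whole section. The genes above the floor were taken anew in each setting. Over the whole section they also held Krt19 and Epcam, so these medians are not over the same 6 genes. Cell cycle genes had a median of -0.29 at percentile 12.7, with Pcna at 0.819, Ccne1 at 1.05, Cdk1 at 0.865 and Ccnb2 2.52-fold lower. The cluster led by cell cycle genes, with 685 mutant and 1102 wild-type cells, stayed unnamed and is not part of these sums. Medians were -0.10 for midlobular genes (percentile 22.6), 0.19 for bile acid synthesis and transport (87.4) and -0.12 for urea cycle and amino acid catabolism (11.2). They were 0.11 for p53 and senescence (59.8) and 0.18 for chromatin genes (74.5). The lists of glutathione and xenobiotic response and of acute phase and stress lay at percentiles 26.9 and 39.9, and 7 of 15 growth factor and Hippo genes had a fold above 1. Single members, with the most counts in their lists, were as follows. Hamp was at 0.991, Hamp2 at 0.936, Igfbp2 at 0.626, Cyp8b1 at 1.41, Ppara at 1.07 and Cyp4a10 at 1.44. The transporters Abcc2 and Slc10a1 were at 1.07 and 0.924, Arg1 of the urea cycle at 0.854, Gsta3 at 0.840 and Gclm at 1.03. Crp was at 1.00, Fgg at 0.989, Atf4 at 1.06, Cdkn1a at 1.08, Fas at 1.06 and Trp53 at 450 against 407 CPM. Arid1a was at 1.15, Bap1 at 1.13, Vegfa at 0.876, Yap1 at 1.00, Notch2 at 0.963 and Fgfr2 at 1.15. Paralogs of the Gsta and Gstp families can share probes' transcripts, so their levels are uncertain. Fgf21, encoding a fasting hormone of the liver, was 2.16-fold lower. Lists with fewer than 3 genes above the floor had no median. They included the clock gene Usp2 (1.27), the Wnt and R-spondin genes Wnt5b (1.07) and Rspo3 (1.14), the male-biased Gstp1 (0.872) and the female-biased Cyp2a4.

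**Figure D1:**
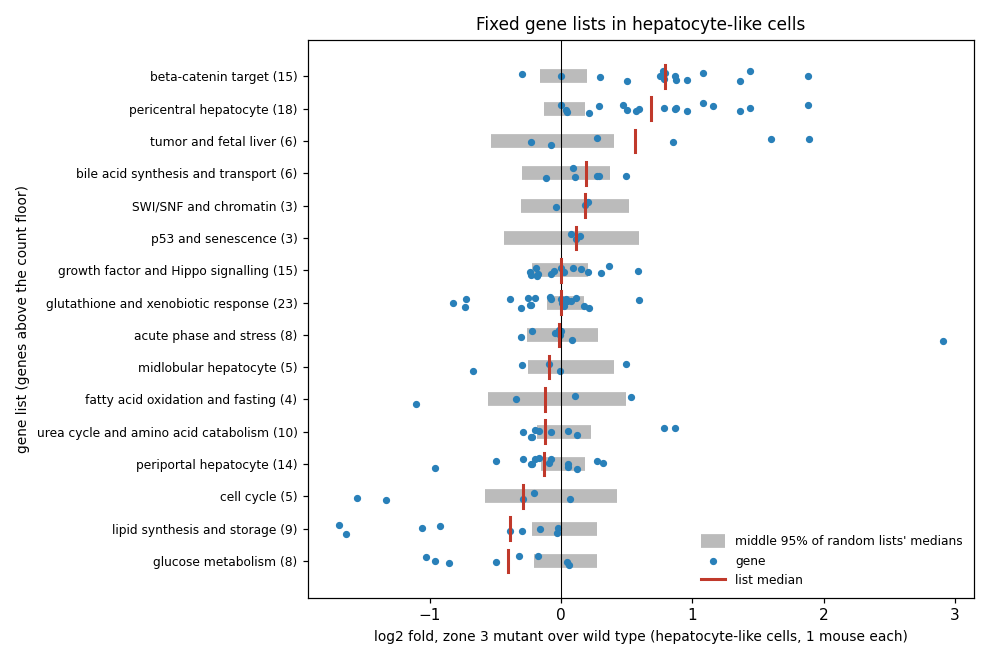
Log2 folds (mutant over wild type) in hepatocyte-like cells on the horizontal axis, by fixed gene list on the vertical axis, with 1 mouse per group. Dots are genes, red bars list medians and grey bands the middle 95% of medians of random matched lists. The medians of the beta-catenin list (0.79), the pericentral list (0.69) and the tumor and fetal liver list (0.56) lie above their bands, and those of the lipid list (-0.39) and the glucose list (-0.41) lie below.

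Of 337 genes above the count floor in hepatocyte-like cells, 12 were at least 2-fold higher and 19 at least 2-fold lower in the mutant. The largest fold was that of Lcn2, encoding the iron-binding acute phase protein lipocalin 2, at 96.8 CPM against 12.9, 7.52-fold higher (7.11 to 7.96). Afp, the fetal liver gene of alpha-fetoprotein, was 3.71-fold higher (3.56 to 3.86), and the dicarboxylate transporter gene Slc13a3 3.68-fold (3.61 to 3.75). The cytochrome genes Cyp2a4 and Cyp2a5 were 3.68-fold and 2.23-fold higher. These are near-identical paralogs whose probes could share transcripts, so their separate levels are uncertain. Saa4 was 3.46-fold higher, Abcb1b 3.32-fold, Spp1 3.03-fold and the cytokine receptor gene Lifr 2.03-fold. Spp1, which cholangiocytes also express, was at only 1.19-fold over the whole section. The other large differences downward were Jag2 (4.31-fold lower), Anxa10 (3.87-fold), Vwf (3.86-fold), Tnc (3.59-fold), Cib3 (3.47-fold), Bub1 (2.94-fold), Lag3 (2.68-fold) and Lpcat4 (2.62-fold). Of these, Vwf was at 14.4 against 55.7 CPM, Jag2 at 5.15 against 22.2 and Anxa10 at 5.68 against 22.0. Bub1 was at 7.88 against 23.2 and Lag3 at 20.4 against 54.7. At these low levels transcripts of neighbouring cells and probe background count. Negative control probes were lower in the mutant too, at 0.718 times the wild type per panel transcript. The highest probe had 3459 and 5877 counts over all cells. Hepatocyte-like counts were 469 and 2473 for Jag2, 517 and 2445 for Anxa10 and 717 and 2579 for Bub1. Vwf, an endothelial gene, was at 1.28-fold in endothelial-like cells.

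Over the whole section 10 genes were at least 2-fold higher and 19 lower among 382 above the floor. Those not already named were all lower: Xcr1 (2.30-fold), Ccl27a (2.20-fold), Hspb1 (2.13-fold), Pklr of glycolysis (2.06-fold) and Krt19 (2.01-fold). Markers of stellate cells and fibroblasts had a median log2 fold of 0.40 at percentile 99.9, with Col1a1 at 1.65-fold (1.62 to 1.69), Hgf at 1.56-fold and Vipr1 at 1.40-fold. Endothelial markers had a median of 0.16 at percentile 94.7, with Eng at 1.22, Egfl7 at 1.13 and Tek at 1.24. The median was 0.07 for macrophage and Kupffer markers (percentile 59.3), with Vsig4 at 1.05 and Csf1r at 452 against 410 CPM. It was -0.26 for cholangiocyte markers (5.83), with Sox9 at 0.833 and Pkhd1 at 0.913, and -0.49 for 4 dendritic markers (5.16), with Ccr7 at 0.526, Clec9a at 0.961 and Siglech at 1.36. It was -0.18 for T and NK markers (41.4), with Tcf7 at 1.59, Klrk1 at 0.937 and Cd4 at 0.833. Tcf7 is also on the beta-catenin list, and 6967 of its 8984 mutant transcripts lay in hepatocyte-like cells. Likewise 12277 of 14993 mutant and 30097 of 34785 wild-type Ccr7 transcripts lay in hepatocyte-like cells, so these values do not describe T, NK or dendritic cells alone. Hepatocyte and erythroid markers lay at percentiles 37.9 and 78.7, with Apob at 1.06, Alas2 at 1.12, Tfrc at 1.19 and Pf4 at 1.01. The B and plasma list had only Xbp1 (1.16) above the floor, the mesothelial list only Krt19, and the neutrophil and neural lists had 0 genes on the panel.

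Cell classes were compared next, from clusters made without the zonation and beta-catenin genes. Hepatocyte-like cells made up 64.9% of mutant cells (64.6 to 65.1) and 63.8% of wild-type cells (63.6 to 64.0). Endothelial-like cells were at 12.4% and 11.8%, stellate and fibroblast-like cells at 8.65% and 8.38%, and macrophage and Kupffer-like cells at 6.29% and 6.26%. Cholangiocyte-like cells were at 1.71% (1.63 to 1.78) and 2.26% (2.19 to 2.34), and T and NK-like cells at 1.45% and 1.72%. The clusters left unnamed held 4.62% and 5.76%. At a resolution 2 times higher, the hepatocyte-like share differed by -7.66 points (mutant minus wild type), since a mutant cluster with 8.67% of its cells stayed unnamed. The endothelial-like difference was reversed to -0.174 points under the per-cell marker rule. The macrophage and Kupffer-like one was -0.930 points at a resolution 2 times lower. The share of a cell class in 1 section also depends on where the section was taken. The 6 hepatocyte-like clusters were nearly specific to 1 mouse each. Clusters 2, 5 and 6 held 29.0%, 18.9% and 16.1% of mutant cells, and clusters 1, 4 and 9 held 30.6%, 21.4% and 10.4% of wild-type cells. Each of the 6 held under 1% of the other mouse's cells.

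In the other classes only genes with at least 2 times the hepatocyte CPM in a section were described, since hepatocyte transcripts can lie inside the outline of a neighbouring cell. In endothelial-like cells 3 genes were at least 2-fold higher and 2 lower. Tnfrsf10b, encoding a death receptor, was at 220 CPM against 23.8, 9.25-fold higher (7.43 to 11.6), while it was at 8.39 and 7.54 CPM in hepatocyte-like cells. Col1a1 was 2.53-fold higher and Timp1 2.41-fold (75 and 35 counts). Il6 was 3.17-fold lower (37 and 132 counts) and Cxcr6 2.26-fold (62 and 158 counts). Of these 5 genes, only Col1a1 was at 4 times its hepatocyte CPM or more in both sections, and Col1a1 is a stellate and fibroblast marker that was at 1.65-fold over the whole section. The 5 measured Wnt and R-spondin genes in these cells had a median log2 fold of 0.13 at percentile 66.6. In stellate and fibroblast-like cells 3 genes were higher and 20 lower. Under a class rule of 4 times in both sections only 1 was higher, and 14 to 21 were lower over the settings tried. Tnfrsf10b was 2.57-fold, Abcb1b 2.18-fold and the Wnt receptor gene Fzd1 2.14-fold higher (2.04 to 2.26). Jag2 was 3.74-fold lower (70 and 276 counts) and Lyve1 3.37-fold. Ctnnd2 was 3.32-fold lower and Il22 2.78-fold, from only 24 and 84 and 29 and 85 counts. Jag2 was also 4.31-fold lower in hepatocyte-like cells. Lyve1 is an endothelial marker. The wild type had more of this class in cluster 11 (2.74% of cells, against 1.90%) and less in cluster 7 (5.64%, against 6.75%). In macrophage and Kupffer-like cells Lcn2 was 3.13-fold (2.26 to 4.39) and Abcb1b 2.07-fold higher. In the mutant, Lcn2 was at 88.1 CPM in these cells and 96.8 in hepatocyte-like cells, and Abcb1b at 45.8 and 34.2, so neither was set apart from transcripts of neighbouring hepatocytes. In the same cells Vwf was 2.45-fold lower (89 and 235 counts) and Klrb1c 2.07-fold (34 and 76). Cdkn2a was 2.02-fold lower (33 and 72 counts) and Bub1 2.01-fold (59 and 128). In cholangiocyte-like cells 0 genes were higher and 11 lower, and 7 were lower under a class rule of 4 times in both sections. The 11 were led by Cxcl10 (4.32-fold, from 30 and 198 counts), Trim16 (3.00-fold, 38 and 174), Myc (2.62-fold) and Ctnnd2 (2.52-fold). In T and NK-like cells Gzmb, encoding granzyme B, was 2.10-fold higher (1.85 to 2.39). Lower were Vwf (3.51-fold, 35 and 164 counts), Xcr1 (2.67-fold, 25 and 89), Notch3 (2.55-fold, 27 and 92) and Gas6 (2.06-fold). The class rule compares CPM, so equal transcripts per cell can pass it in a shallow class. Vwf was at 0.0198 and 0.0611 transcripts per cell in T and NK-like cells and 0.0167 and 0.0624 in hepatocyte-like cells. Jag2 was at 0.00666 and 0.0211 in stellate and fibroblast-like cells and 0.00595 and 0.0249 in hepatocyte-like cells. The lower Vwf and Jag2 were thus not set apart from neighbouring transcripts or background.

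Zonation was described by ranking hepatocyte-like cells within each section into 10 equal bins, from periportal to pericentral, by the balance of pericentral and periportal transcripts among 50 per cell. All 78810 mutant and 99422 wild-type hepatocyte-like cells had this depth. Bins are ranks of a score within each section and not positions in the tissue, and the gene described was left out of its own score. The same bin can span different scores in the 2 sections. The median score was -1.32 in the mutant and -2.50 in the wild type, and the 90th percentile 2.22 and 0.778. Values of the same bin therefore do not compare matched zones. In the wild type, Glul was concentrated in the most pericentral bin, which held 65.6% of its transcripts (65.2 to 66.0). In the mutant it held 48.2% (47.9 to 48.5) and the next bin was also high. Glul was at 72940 CPM in bin 9 of the mutant against 13798 in the wild type, and at 122445 against 82877 in bin 10. Axin2 was at 1687 CPM against 467 in bin 10 and at 9.36 against 8.42 in bin 1. Lgr5 was at 1321 against 549 in bin 10 and Tbx3, a transcription factor, at 2025 against 909. Oat was at 52611 against 32520 in bin 10. Cyp2e1 was at 89150 against 92424 in bin 10 but at 37545 against 11877 in bin 5, and Cyp1a2 was at 21182 against 28181 in bin 10 and 6170 against 2603 in bin 5. The periportal genes Cyp2f2, Hal, Sds and Gls2 peaked in bin 1 of both sections. In bin 1 the folds of Cyp2f2, Hal and Gls2 were 1.18, 1.11 and 0.963, and Sds was at 14734 against 13362 CPM. Pck1 was at 36609 against 45254 CPM in bin 1 and at 4648 against 18343 in bin 10.

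**Figure D2:**
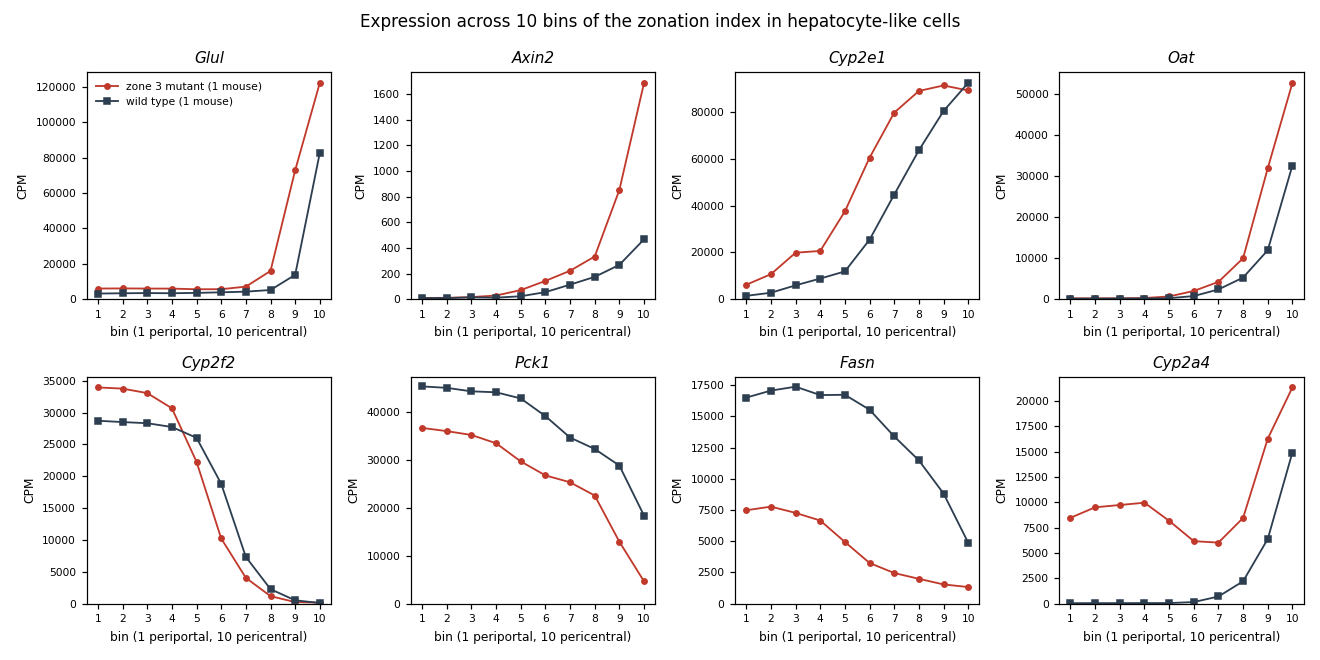
CPM of 8 genes (vertical axes, starting at 0) across 10 bins of the zonation index (horizontal axes, 1 periportal and 10 pericentral) in hepatocyte-like cells of the mutant (red circles) and the wild type (dark squares), 1 mouse each. Cells were ranked into bins within each section. Glul reaches 72940 CPM in bin 9 of the mutant against 13798 in the wild type, and Cyp2a4 is at 8470 against 51.3 in bin 1; Fasn and Cyp2a4 were chosen for the plot after their values were seen.

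Glul made up at least 5% of the transcripts of 16.3% of mutant hepatocyte-like cells (16.1 to 16.6) and 7.40% of wild-type cells (7.24 to 7.57), a level chosen after the values were seen. Few cells lay near it, with 1.47% and 0.452% of cells between 4% and 6%. The medians over cells were 0.637% and 0.389%. At 50 transcripts per cell, 39.1% of mutant and 24.8% of wild-type hepatocyte-like cells had a Glul transcript, and 97.0% and 92.1% without thinning. The thinned share was higher in endothelial-like cells, at 65.6% and 50.2%, so a Glul transcript was not specific to hepatocyte-like cells. Whether those transcripts came from neighbouring hepatocytes or from the endothelial-like cells themselves was not tested. The endothelial-like shares are therefore no measure of transcripts of neighbours in hepatocyte-like cells. The median depths were 1070 and 1039 transcripts in hepatocyte-like cells and 173 and 156 in endothelial-like cells. Axin2 was found in 1.58% (1249 cells) and 0.551% (548 cells) of thinned hepatocyte-like cells, against 1.06% and 0.664% of endothelial-like cells. Lgr5 was found in 1.32% and 0.465%, against 0.382% and 0.202%, and Tbx3 in 2.05% and 1.03%, against 0.845% and 0.551%. Glul together with Cyp2f2 was found in 11.1% and 7.48% of hepatocyte-like cells, which was 0.651 and 0.644 times the share that independent detection would give. In endothelial-like cells the pair was found in 14.6% and 11.9%. In hepatocyte-like cells the ratio to independent detection was 0.640 and 0.632 for Glul with Hal and 0.649 and 0.631 with Sds. With Pck1 it was 0.764 in the mutant and 0.886 in the wild type.

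Lobule polarity was measured as the Spearman correlation, across hepatocyte-like cells, of the pericentral and periportal transcript shares at 50 transcripts per cell. It was -0.816 in the mutant and -0.732 in the wild type. Cells are not replicates, so no test was made. The pericentral list without Glul made up 11.3% of thinned transcripts in the mutant and 7.60% in the wild type, and the periportal list 22.0% and 25.8%. The correlation also depended on depth. From 30 transcripts per cell to no thinning, it went from -0.752 to -0.948 in the mutant. In the wild type it went from -0.659 to -0.902. Since the list shares differed between the sections and are parts of the same total, the more negative mutant value cannot be read as stronger polarity.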

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

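The tests in this part were all chosen after the values were seen. Features that match no gene were set against panel transcripts. The comparisons of the report use none of the codewords among them, and use the negative control probes only for the count floor. Negative control codewords, which no probe carries, were at 56.9 CPM in the mutant and 39.8 in the wild type, relative to panel transcripts, a ratio of 1.43 (counting interval 1.38 to 1.49). Unassigned codewords were at 34.8 and 26.0, a ratio of 1.34 (1.28 to 1.41). Both were listed because the mutant section exceeded the control section. Negative control probes went the other way, at 61.4 and 85.6, a ratio of 0.718 (0.695 to 0.741), and at 0.717 without the highest probe, which held 55.9% of probe counts in each section. All 3 kinds were rare beside panel transcripts as a whole. The highest probe, with 3459 and 5877 counts over all cells, still exceeded the hepatocyte-like counts of some genes described as lower, such as Jag2 (469 and 2473). The cause of the opposite directions of the 3 kinds was not tested.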

How the results depend on the processing

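The floor from the median negative control probe and thinning to 300 were chosen after seeing the data, and the other alternatives before the data were examined. No paired analysis was possible because each group has 1 sample. Values are given in the order beta-catenin, pericentral, periportal and lipid list, as median log2 folds. They were 0.84, 0.73, -0.0888 and -0.35 with TMM factors, 0.84, 0.73, -0.0875 and -0.35 with mean transcripts per cell, and 0.74, 0.63, -0.19 and -0.44 without the 10 highest genes in the totals. Without the 2% of cells with the most transcripts they were 0.84, 0.73, -0.14 and -0.35. With median of ratios the pericentral and periportal medians were 0.71 and -0.11. The periportal and lipid medians were -0.14 and -0.31 under the per-cell marker rule and in the whole section. The tumor and fetal liver median, 0.56 in the main setting, was reversed to -0.12 in the whole section and was 0.13 under the marker rule, 0.29 with no floor, 0.28 with the floor from the median probe and 0.51 without the 10 highest genes. Its genes above the floor were taken anew in each setting, so these medians can be over different genes. Over 13 settings 10 to 15 genes were higher and 17 to 27 lower in hepatocyte-like cells. With TMM, 12 of the 12 higher and 17 of the 19 lower genes were shared, and without the 10 highest genes 11 and 19 were.

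The folds of Ctnnb1, Arid2 and Cyp1a2 were 1.01, 1.01 and 1.03 with mean transcripts per cell and 1.01, 1.00 and 1.03 with TMM, on the other side of 1. The hepatocyte-like share differed by -7.66 points at a resolution 2 times higher, a reversal made by a cluster with 8.67% of mutant and 0.0706% of wild-type cells that stayed unnamed, and by 2.29 points under the marker rule. The endothelial-like difference was reversed to -0.174 points under the marker rule and was 0.0752 at a resolution 2 times lower. The macrophage and Kupffer-like difference, 0.0322 in the main setting, was -0.930 at the lower resolution and -0.433 under the marker rule, and the stellate and fibroblast-like one, 0.272, was 0.624 and 0.592 at the higher and lower resolution. The cause was not tested.

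Thinned to 30, 100, 300 and not at all, the top bin held 46.1%, 50.04%, 51.2% and 49.0% of Glul transcripts in the mutant and 60.9%, 69.7%, 71.8% and 74.7% in the wild type. The share of hepatocyte-like cells with Glul was 30.8%, 54.1%, 83.2% and 97.0% in the mutant and 18.2%, 38.0%, 69.6% and 92.1% in the wild type, so it depended on depth. Polarity was -0.752, -0.877, -0.927 and -0.948 in the mutant and -0.659, -0.807, -0.876 and -0.902 in the wild type, and -0.735 and -0.628 at 50 without Cyp2e1 and Cyp2f2. With the periportal list only, the top bin of the wild type held 63.9%, and without beta-catenin targets in the index the top bins held 47.7% and 62.5%. Under each of these settings the Glul share of the top bin was lower in the mutant and the polarity more negative. The top bin always holds 10% of cells, while 16.3% of mutant and 7.40% of wild-type cells had at least 5% Glul transcripts. The lower share in the mutant thus follows in part from the bin size under each setting. The more negative polarity was not set apart from the different shares of the pericentral and periportal lists under any setting.

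With a class rule of 4 times in both sections, endothelial-like cells had 1 higher and 0 lower genes, macrophage and Kupffer-like cells 0 and 2, stellate and fibroblast-like cells 1 higher and cholangiocyte-like cells 7 lower. With CPM over class-rule genes only, cholangiocyte-like cells had 1 higher and 7 lower genes. Of the other values, 73 for main results and 49 for single lists, genes or classes stayed within the counting interval or within 1.5 times the count. Beside these 73, 66 values for main results moved by more than that and 1 was reversed. For single lists, genes or classes 24 moved by more than that, those of the tumor and fetal liver list and of the classes above among them.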

Other observations

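The tests of pericentral tissue, of Cyp2a5 transcripts (over all and over the most pericentral cells) and of sex were chosen only after the results were seen, and each pattern was found and tested on the same 2 sections.

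The lipid list was lower in mutant hepatocyte-like cells under each scaling tried, with a median of at most -0.35. The other scalings shifted all log2 folds by only -0.0533 to 0.0447. The choice among them therefore does not account for the difference, and scalings further from these were not tried. In the most periportal bin the median was -0.59, with 6 of 9 folds below 1 and 3 above, which argues against a difference limited to pericentral cells. Fasting of the mutant mouse would raise Pck1 and G6pc, but the higher of both folds in that bin was 0.809, so no such rise was seen. Both genes are also on the periportal list, and other differences between the mice could lower them, so this cannot exclude fasting. A difference in strain, hour of collection or food before collection may contribute, as may the genotype, and these were not tested.

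Beta-catenin targets were higher under each scaling tried, with a median of at least 0.74. The same small shifts between scalings apply here. More pericentral tissue in the mutant section would change the number of Glul-rich cells but not their content. Glul was left out of the totals of the 12870 mutant and 7361 wild-type cells with at least 5% Glul transcripts. Among these cells 12 of 14 other targets had a fold above 1, with a median log2 fold of 0.92. This argues against more pericentral tissue as the whole cause. The genotype, the strain and differences between single mice were not tested apart and stay open, since each group has 1 mouse.

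Cyp2a4 was at 8470 CPM in the most periportal bin of the mutant and 51.3 in that of the wild type, values chosen after they were seen. If the Cyp2a4 probes read only Cyp2a5 transcripts, the ratio of both would be the same in each section, but mutant over wild type was 1.65 (1.64 to 1.66). The ratio was 4.35 against 0.967 in the most periportal bin, but 0.788 against 0.842 in the most pericentral one, or 0.936 times the wild type, so this explanation stays open for pericentral cells. Whether the Cyp2a5 probes read Cyp2a4 transcripts was not tested. Cyp2a4 is female-biased, and with sex not given, and strain not tested, a female mutant and a male wild type may give this pattern. The male-biased gene on the panel, Gstp1, was at 0.872, between 2 cut-offs that were chosen after values were seen. Its level is also uncertain because Gstp paralogs can share transcripts. Sex and genotype therefore cannot be told apart here.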
